A study of Mus musculus with 2 samples.

How the data were processed

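H3K4me1 ChIP-seq peaks were analysed for 2 biological replicates of mouse kidney at postnatal day 0, each a pool of tissue from both sexes, per the labels. The labels give a size range of 300 to 500, without a unit. The 4 peak lists in narrowPeak format used here are on build mm10. Per the text deposited with the samples, the lists hold the peaks of replicate 1 (technical replicates together), the peaks of replicate 2, the peaks of both replicates pooled, and replicated peaks derived from the other lists. That text says each list was derived from alignments together with further files, whose content it does not name. The aligner, the peak caller, its version and threshold, and the read depth are not given in the sources used here. The labels name a possible control experiment, which was not used here.

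The deposited score of each peak (column 5) runs from 0 to 1000 within a list and was not used in any test. The deposited signal value (column 7) is the caller's measure of enrichment, on a scale that is not stated, and was used to rank peaks within a list and to correlate the replicates. The deposited −log10 p and −log10 q values (columns 8 and 9) were used to rank peaks and to filter at a −log10 q of at least 3. The lowest −log10 p was close to 2 in each list, so that the lists hold many weak peaks. In the pooled list 45.2% of peaks had a −log10 q of at least 3, in the replicated list 73.7%, in replicate 1 26.4% and in replicate 2 13.5%. All replicated peaks were identical to a pooled peak, and 22.9% of them did not overlap a peak in both replicates by at least 50% of either peak. Peak lists without read counts cannot show how depth differed between the replicates, and a deeper library can give more, wider or narrower peaks, so peak numbers and widths were not tested between replicates.

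Genes came from the GENCODE mouse release M21 annotation of the same build, and all peaks on the assembled chromosomes ended within their lengths. Protein-coding genes on the 19 autosomes and X were used, 21728 in all, with the longest kept where a symbol occurred more than once. Coordinates are 1-based. Peaks and genes were joined with own interval code in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. bedtools, foreseen for the overlaps, was not used.

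Overlap between replicates was the share of a replicate's peaks with at least 50% of their length covered by the other's, and was compared with 100 circular shifts of the other replicate's peaks within each chromosome by 5% to 95% of its length. Peak midpoints were assigned to promoters (within 1 kb of any start of a protein-coding transcript), exons, introns or intergenic sequence, in that order, and compared with 100 shifts in the same way. Around the most upstream start of each gene, coverage was computed in bins of 100 bp to 5 kb on each side, and coverage at the start was compared with that at 1 to 2 kb through the mean difference over genes, with 10000 flips of the sign of whole blocks of 1 Mb and a bootstrap over the 2289 blocks. This test was chosen after the data were seen, in place of an exact sign test over genes. The start is a window of 200 bp and the flanks are 2000 bp, and the sign test had p under 0.05 in all 100 lists of shifted peaks, with 3.05 genes higher in the flanks for each gene higher at the start, whereas the flips had p under 0.05 in 5 of the 100. For each gene, the percent of its body and 20 kb on each side covered by replicated peaks was computed. The median over each of 17 gene lists was compared with 10000 random lists of the same size, drawn with replacement from genes outside the list in 20 classes of gene length, with a two-sided p and Benjamini-Hochberg adjustment over the lists. Genes of the 7 kidney lists and of the 5 other-organ lists were compared by 100000 permutations of the gene labels. Genes are not independent replicates, and neighbouring genes share flanks.

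The lists, the rule for named genes, and the tests and alternatives other than those said to be chosen or added after the data were seen were fixed before the data were examined. The lists are nephron progenitors, differentiating nephron, podocytes, proximal tubule, loop of Henle and distal tubule, ureteric bud and collecting duct, renal stroma, endothelium, macrophages and lymphocytes, erythroid cells, adrenal gland, hepatocytes, neurons, striated muscle, lung epithelium, housekeeping genes and olfactory receptors. The rule names the 3 most covered members and the least covered member of each list except olfactory receptors, the 10 most covered genes of at least 10 kb, and the genes nearest to the 10 strongest and the 10 widest replicated regions. Where several members lie at 0%, 1 of them is named. The groups hold fewer than 3 samples, so no test between groups, check for outlying samples or other split of the samples was run.

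The alternatives were a −log10 q of at least 3, pooled peaks, the peaks of either replicate alone, other overlap rules, equal numbers of top peaks, a promoter window of 2.5 kb, every annotated transcript start, flanks of 5 and 50 kb, peaks per 10 kb, no matching on length and permutation within 5 classes of gene length. Autosomal genes alone were added after the data were seen.

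The methods were tested on simulated data. Of replicate 1 peaks, 40.6% were found shared where 40% were planted. In a simulation of the genomic distribution, 21.9% of peaks were found in promoters where 22.0% were expected. Of lists with peaks planted over 5% of each gene, 100% were recovered. With covered shares permuted among genes of similar length, 4.25% of 1200 unchanged lists of 14 genes had a p under 0.05. The first 200 of these, drawn before the number was raised, gave 8.5%. Of 100 lists of 14 genes raised by 4 percentage points, 93% had a p under 0.05. These p were not adjusted, whereas the gene lists were judged on adjusted p and some are smaller. A list difference of this size or smaller can therefore be missed. For the comparison of kidney with other-organ genes, 5% of unchanged sets and 88% of sets raised by 2 percentage points had a p under 0.05.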

Results

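Histone H3 monomethylated at lysine 4 (H3K4me1), a chromatin mark found at enhancers and beside promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole kidneys of mice at postnatal day 0, when the mouse kidney still forms nephrons. The samples formed 1 group of 2 biological replicates without a treatment or a second tissue. Each replicate was a pool of tissue from male and female animals. Replicate 1 held tissue from 15 mice and joined 2 technical replicates, and replicate 2 held 1 technical replicate from a pool of unstated size. Deposited peak lists, 4 in all, on the mouse build mm10 were examined, comprising the peaks of each replicate, the peaks of both replicates pooled, and a list of replicated peaks. Read depth is unknown from these lists, so no counting interval was given. With 1 group of 2 pools, p-values below compare genes or positions within these libraries and do not describe variation among animals.

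Replicate 1 had 108970 peaks with a median width of 322 bp, which covered 45.2 Mb. Replicate 2 had 124996 peaks with a median width of 232 bp, which covered 35.8 Mb. The pooled list held 133465 peaks. The replicated list held 64302 peaks with a median width of 452 bp and covered 35.7 Mb, or 1.31% of the genome. It is the list used below unless another is named.

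Genes of the differentiating nephron had the highest median H3K4me1 peak coverage among the kidney gene lists, which were not tested against each other. For each gene, the share of its body and 20 kb on each side that was covered by replicated peaks was computed, and each list's median was compared with 10000 random lists of equal size matched on gene length. The median of the 12 differentiating nephron genes was 7.64%, against 1.33% for the random lists (adjusted permutation p = 0.0068, Benjamini-Hochberg over 17 lists). All 12 genes were covered, 10 of them above the median of genes of similar length, and the list's median was 10.1% in replicate 1 and 6.09% in replicate 2. Pax8, a paired-box transcription factor of the early nephron, was covered over 17.1% of its territory. Fgf8, a growth factor of the early nephron, reached 12.5% and Jag1, a Notch ligand, 11.5%, while Bmper was lowest at 0.590%. With a flank of 50 kb in place of 20 kb, the list's median was 4.16% and no longer passed the test (adjusted permutation p = 0.175). Random lists were matched on length but not on the kind of gene, and their pool held the olfactory receptors. Hox genes (median 24.9%) and cytosolic ribosomal protein genes (3.97%) also lay above such lists. The result therefore does not show that high coverage is particular to genes of the nephron.

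The other kidney lists did not pass the adjusted threshold under the main settings. The 18 genes of the ureteric bud and collecting duct had a median of 4.55% (6.11% in replicate 1 and 4.19% in replicate 2; adjusted permutation p = 0.0895), with all 18 covered and 13 above the median of genes of similar length. Hoxb7 was covered over 24.9%, the keratin gene Krt8 over 9.61%, Wnt11, a ligand made at ureteric bud tips, over 9.27%, and Scnn1g, an epithelial sodium channel subunit, over 0.443%. This list passed with the peaks of replicate 2 alone (4.19%, adjusted permutation p = 0.0397) and with a flank of 5 kb (6.74%, adjusted permutation p = 0.0125), but its median was 2.58% among peaks with a −log10 q of at least 3 (adjusted permutation p = 0.304) and 3.07% with a flank of 50 kb (adjusted permutation p = 0.424). The 14 genes of nephron progenitors had a median of 3.77% (6.34% in replicate 1 and 2.92% in replicate 2; adjusted permutation p = 0.220), and passed with a flank of 5 kb (7.40%, adjusted permutation p = 0.0272). Its median was 1.69% among peaks with a −log10 q of at least 3 (adjusted permutation p = 0.842) and 1.76% with a flank of 50 kb (adjusted permutation p = 0.899). Of the nephron progenitor genes, 13 were covered, led by Hoxc11 at 15.0%, Meox1 at 13.9% and Hoxd11 at 12.1%. Cited1, on chromosome X, was covered at 0%.

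The 14 podocyte genes had a median of 3.02% (4.91% and 3.07% in replicates 1 and 2; adjusted permutation p = 0.220), and 13 were covered. Synpo, which encodes an actin-associated protein of podocyte foot processes, reached 18.9% with 33 peaks, Kirrel 11.8% and Foxc2 10.7%, while Cd2ap was at 0%. The 18 genes of renal stroma had a median of 2.56% (3.74% and 2.40%; adjusted permutation p = 0.305), and 15 were covered. Pbx1, a homeobox transcription factor, carried 89 peaks over 15.8% of its territory, the collagen gene Col1a1 was covered over 9.56%, Meis2 over 6.46%, and Dcn at 0%. For the 18 proximal tubule genes the median was 2.09% (2.64% and 2.07%; adjusted permutation p = 0.753), with 16 covered. Pck1, a gluconeogenic enzyme gene, reached 12.2%, Ggt1 11.9% and Amn 5.92%, and the organic anion transporter gene Slc22a6 was at 0%. The 14 genes of the loop of Henle and distal tubule had a median of 1.38% (1.47% and 1.16%; adjusted permutation p = 0.953), with 11 covered. Their highest values were 4.71% for Irx2, 4.16% for Pou3f3 and 4.01% for Slc12a3, the thiazide-sensitive cotransporter gene, and Cldn16 was at 0%.

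**Figure D1:**
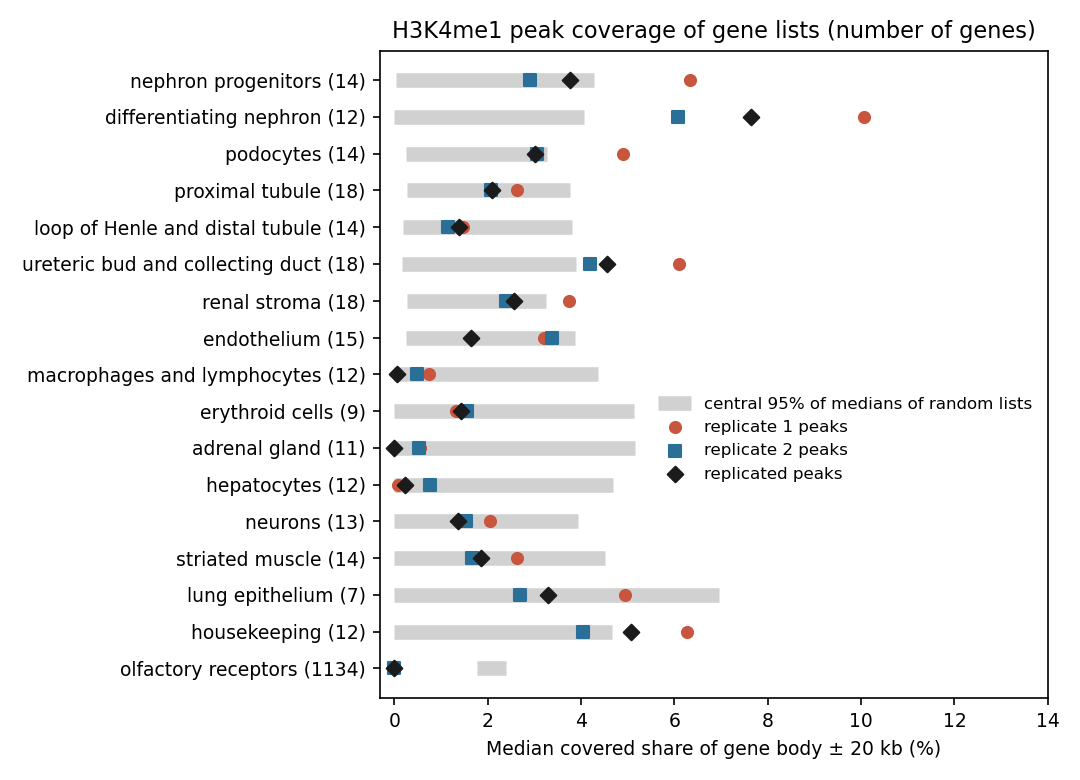
Median share of gene body and 20 kb flanks covered by H3K4me1 peaks (x axis, percent) for each gene list (y axis, number of genes in brackets). Diamonds are replicated peaks, circles and squares the peaks of replicates 1 and 2, and grey bars the central 95% of medians of 10000 length-matched random lists for replicated peaks only. The differentiating nephron list lies at 7.64%, and the 1134 olfactory receptors at 0%.

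At Pax8 (ENSMUSG00000026976.15, reverse strand, chromosome 2, 24420560 to 24475599, mm10), 26 replicated peaks covered 16210 bp of the gene and its flanks. The covered share was 15.8% with the peaks of replicate 1 and 16.6% with those of replicate 2. A group of peaks from 24453261 to 24469173 lay within 1 intron, between the exon ending at 24444731 and the exon beginning at 24475073. The widest single peak of the region, from 24416249 to 24418029, lay beyond the 3′ end of Pax8, between it and Psd4.

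**Figure D2:**
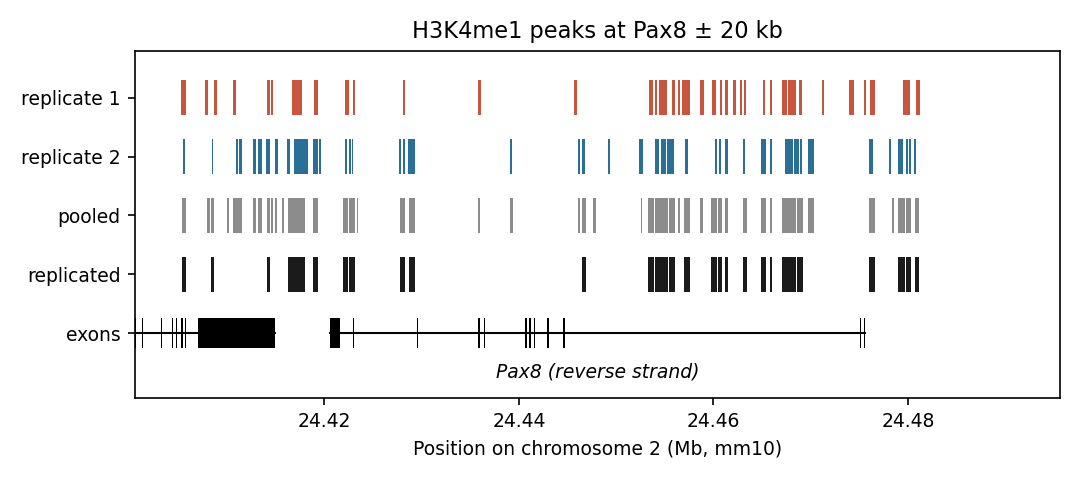
H3K4me1 peaks of the 4 lists (rows) and exons of Pax8 and of its neighbour Psd4, at the left, along chromosome 2 (x axis, Mb, mm10), from 20 kb beyond each end of Pax8. The replicated list held 26 peaks here.

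None of the 5 lists of other organs passed the test. The 11 adrenal genes, chosen because the adrenal gland lies on the kidney, had a median of 0% (0.555% and 0.528% in replicates 1 and 2; adjusted permutation p = 0.357). Of these, 4 were covered, with Nr5a1 at 4.08%, Star at 1.51%, Cyp11a1 at 0.797% and Chga at 0%. The 12 hepatocyte genes had a median of 0.234% (0.0855% and 0.757%; adjusted permutation p = 0.247), with 6 covered. F2 reached 2.20%, Apoh 1.71% and Apoa1 1.52%, and Ahsg was at 0%. The 13 neuronal genes had a median of 1.37% (2.06% and 1.54%; adjusted permutation p = 0.953), led by Grin1 at 8.42%, Neurod2 at 7.73% and Dlx1 at 7.69%, and Neurod6 was at 0%. The 14 striated muscle genes had a median of 1.85% (2.63% and 1.67%; adjusted permutation p = 0.953), but Tnnt3 was covered over 17.7%, Myl7 over 13.8% and Tnni3 over 8.79%, while Myh3 was at 0%. The 7 lung epithelium genes had a median of 3.30% (4.95% and 2.70%; adjusted permutation p = 0.598), with Foxj1 at 14.5%, Scgb1a1 at 9.72%, Sftpc at 6.04% and Sftpb at 0%.

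Among shared cell types, the 15 endothelial genes had a median of 1.65% (3.203% and 3.38%; adjusted permutation p = 0.953). All 15 were covered, with Plvap at 11.3%, Esam at 9.72%, Egfl7 at 8.30% and Emcn at 0.185%. The 12 genes of macrophages and lymphocytes had a median of 0.064% (0.737% and 0.485%; adjusted permutation p = 0.194), with Cx3cr1 at 3.96%, Spi1 at 3.11%, Csf1r at 2.03% and Fcgr3 at 0%. The 9 erythroid genes had a median of 1.44% (1.32% and 1.57%; adjusted permutation p = 0.953), with Klf1 at 5.68%, Slc4a1 at 2.92%, Ank1 at 2.14% and Alas2, on chromosome X, at 0%. The 12 housekeeping genes had a median of 5.06% (6.27% and 4.04%; adjusted permutation p = 0.111), with Gapdh at 14.5%, Actb at 13.3% and Rpl13a at 10.8%, and Hprt, on chromosome X, was at 0%. Olfactory receptor genes, whose expression is largely restricted to the olfactory epithelium, lay below random lists (median 0% against 2.08%, adjusted permutation p = 0.0034), and 43 of 1134 were covered.

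Taken over all lists of each kind, the 108 kidney genes had a median covered share of 3.004%, against 0.989% for the 57 genes of other organs. The difference was 2.01 percentage points (permutation test over gene labels, two-sided, p = 0.0085). It was 1.67 points with the peaks of replicate 2 alone and 2.81 points with those of replicate 1 alone. The size of the difference depended on the peak set and the flank, being 3.47 points with pooled peaks, 3.24 points with a flank of 5 kb and 1.10 points with a flank of 50 kb. Permuted within classes of gene length, p was 0.0393. The sets were not matched on the kind of gene. Medians of the kidney lists ran from 1.38% for the loop of Henle and distal tubule to 7.64% for the differentiating nephron. The housekeeping genes, at 5.06%, lay above the median of the kidney genes. The difference therefore does not show that coverage is particular to kidney genes.

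Across all 21728 protein-coding genes, 15218 (70.04%) were covered to some extent, with a median of 1.39%. Among genes of at least 10 kb, the most covered was Ski, a repressor of TGF-β signalling, at 48.5%, followed by Cxxc5 at 47.2%, Hoxb3 at 47.1%, the thyroid hormone receptor gene Thra at 44.1% and Hoxa3 at 42.0%. Midn (40.4%), Trim8 (40.2%), Gm28308 (39.4%), the retinoic acid receptor gene Rara (37.0%) and Bahcc1 (36.8%) completed the 10 highest. Gm28308 and Hoxa3 overlap, so their values rest on the same 48 peaks. Ski was covered over 47.5% in replicate 1 and 40.8% in replicate 2, and Hoxb3 over 50.4% and 32.8%.

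The strongest replicated peak, by the signal value that the authors' peak caller gave, lay at Hdac5, a histone deacetylase gene (chromosome 11, 102218964 to 102219962, signal 7.71), within 1 kb of an annotated start. The next strongest lay in introns of Plxnb2 (chromosome 15, 89176612 to 89178883, signal 7.26), Bcar1 (chromosome 8, 111732400 to 111737561, signal 7.26) and Zfp608 (chromosome 18, 54952254 to 54953435, signal 7.19). Introns of Ahdc1 (signal 7.06), Rara (6.96), Tmem94 (6.96), Ypel2 (6.95), Smad7 (6.95) and Glis2 (6.92) held the remaining peaks among the 10 strongest. All 10 overlapped peaks in both replicates. Positions relative to introns and starts are those of peak midpoints, so a peak placed in an intron can also span exons.

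The widest replicated region spanned 8334 bp, with its midpoint in an intron of Cxxc5 (chromosome 18, 35836946 to 35845279). It was covered over 98.7% by peaks of replicate 1 and over 90.1% by peaks of replicate 2. Introns of Smad7, an inhibitor of TGF-β signalling (chromosome 18, 75385964 to 75393055, 7092 bp), and of the receptor gene Notch1 (chromosome 2, 26484915 to 26491590, 6676 bp) held the midpoints of the next widest. The other 7 of the 10 widest regions also had their midpoint in an intron and ranged down to 5363 bp. They lay in Tns1, Sept9, Lhfpl2, Ski, Bcar1 and Zmiz1, and in an intron of Bop1 where Scx has the nearest start.

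By position in genes, 53.0% of replicated peaks (34100) had their midpoint in an intron and 26.1% (16790) between genes. A further 17.2% (11090) lay within 1 kb of a start site of a protein-coding gene and 3.61% (2322) in an exon. Compared with peaks shifted along each chromosome, promoters held 6.70 times as many, exons 1.48 times, introns 1.47 times and intergenic sequence 0.444 times. Each of the 4 differences was larger than in any of 100 shifts (two-sided permutation p = 0.0198, the smallest that these can give). The promoter ratio was 5.87 with the peaks of replicate 1 alone and 5.01 with those of replicate 2 alone. With a promoter window of 2.5 kb, the exon ratio fell to 1.12 and did not pass (permutation p = 0.0792). The median distance of a replicated peak to the nearest start site was 11.7 kb, and 11.02% of peaks lay more than 100 kb away.

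Around start sites, H3K4me1 coverage was highest on the downstream side. Replicated peaks covered 6.52% of the 21728 start sites, and 9.28% of positions at 1 to 2 kb averaged over both sides, a difference of 2.76 percentage points. The excess came from the downstream side, where coverage at 1 to 2 kb was 13.5%, whereas upstream it was 5.02%, below that at the start. The 95% bootstrap interval of the difference over blocks of 1 Mb was 2.34 to 3.14 points (permutation p = 0.0001, two-sided, the smallest that 10000 flips of the sign of whole blocks can give). The difference was 2.01 points in replicate 1 alone and 2.53 points in replicate 2 alone. Nearer to the start, the profile peaked at 9.50% at 550 bp upstream and at 17.4% at 950 bp downstream. Genes are not independent replicates, and blocks were used because neighbouring genes share peaks.

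**Figure D3:**
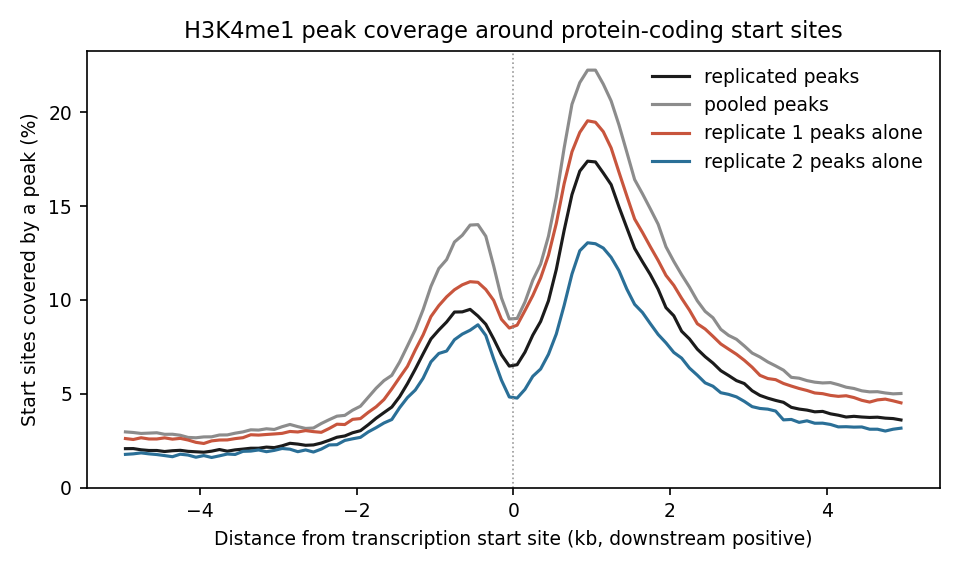
Share of protein-coding start sites covered by an H3K4me1 peak (y axis, percent) by distance from the start (x axis, kb, downstream positive) in bins of 100 bp, with 1 line per peak list. All 4 lists dip at the start. The replicated list peaks at 9.50% upstream and 17.4% downstream.

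Chromosome X held far fewer peaks than any autosome. Its density was 0.661 replicated peaks per Mb, against 17.9 on chromosome 3, the lowest autosome, and 43.5 on chromosome 11, the highest. The lowest autosome exceeded X by 27.0 times in the replicated list, 11.9 times with the peaks of replicate 1 alone, 17.4 times with those of replicate 2 alone and 19.2 times in the pooled list. On X, 81 of 948 genes (8.54%) were covered, against 72.8% of autosomal genes. The low values of Cited1, Alas2 and Hprt given above are those of genes on this chromosome. Leaving out genes on X took the kidney genes from 108 to 107 and left the 57 other-organ genes unchanged. The difference between kidney and other-organ genes was then 2.03 percentage points (permutation p = 0.0079). With so few genes left out, it could change little.

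**Figure D4:**
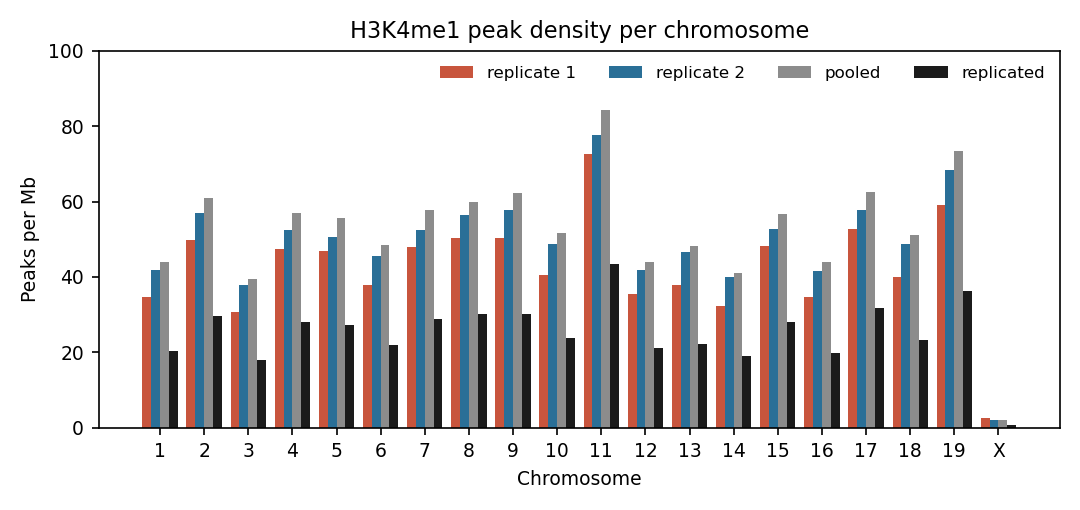
H3K4me1 peaks per Mb (y axis) on each chromosome (x axis), with 1 bar per peak list. In the replicated list, chromosome X has 0.661 peaks per Mb and the autosomes 17.9 to 43.5.

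Between the replicates, 29.8% of the peaks of replicate 1 had at least 50% of their length covered by peaks of replicate 2, against 1.30% on average after shifting. In the other direction, 39.2% of the peaks of replicate 2 were shared, against 1.85%. The base-pair Jaccard index, the shared length over the joint length, was 0.238, against 0.00829 (permutation p = 0.0099 for each, one-sided, the smallest that 100 shifts can give). The shared share depended on the overlap required, being 49.6% and 48.9% with 1 bp, 22.1% and 19.3% with 50% of both peaks, and 6.56% and 21.6% with 90% of the query peak. Among peaks with a −log10 q of at least 3, the shares were 15.6% and 41.1%. This filter left 28725 peaks in replicate 1 and 16921 in replicate 2, so the peaks of replicate 1 were matched against a smaller list. With equal numbers of top peaks, 108970 in each replicate, the shares were 27.4% and 41.0%. This number keeps all peaks of replicate 1 and drops only the weakest of replicate 2, so the setting is close to the main one. Sharing fell with peak rank, from 56.5% in the strongest 10% of replicate 1 peaks to 17.1% in the weakest 10%, and from 68.4% to 26.2% in replicate 2.

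**Figure D5:**
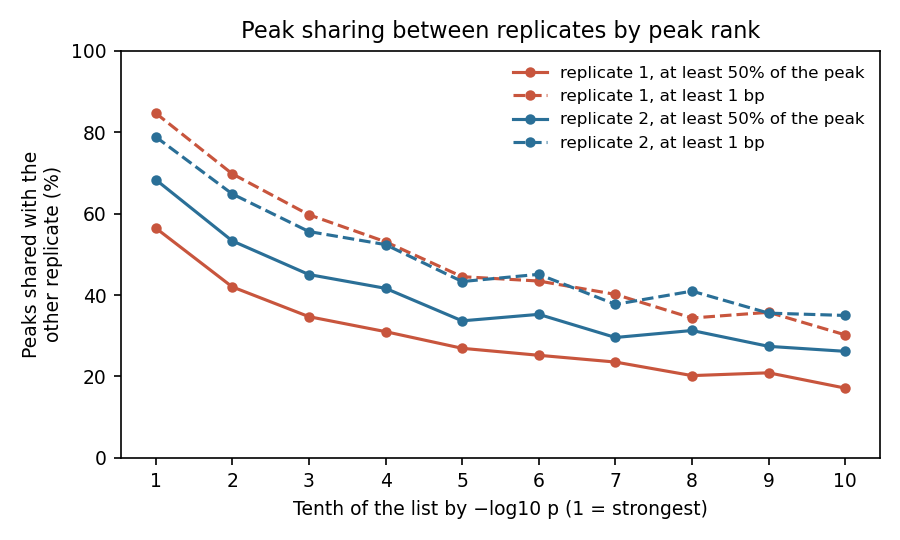
Share of each replicate's peaks that overlap a peak of the other (y axis, percent) in 10 equal parts of the list ranked on −log10 p (x axis, 1 is strongest). Solid lines require 50% of the peak and dashed lines 1 bp, and the solid lines fall from 56.5% to 17.1% in replicate 1 and from 68.4% to 26.2% in replicate 2.

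Over 27831 pairs of overlapping peaks, the log2 signal values of the replicates had a Spearman correlation of 0.26 and a Pearson correlation of 0.28. Summed over genes, the covered share per gene had a Spearman correlation of 0.934 across the 21728 genes. The measures are unlike, since signal was compared only over peaks called in both replicates, whereas the genes include many that no replicated peak covered. Both correlations are across regions or genes, which are not independent replicates, so no p-value was attached to them. Of the replicated peaks, 77.1% overlapped a peak of both replicates by at least 50% of either peak, and 355 touched a peak of neither replicate.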

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

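Of 218 values recomputed under the alternatives, 197 kept their direction and their side of the threshold or moved little, 2 no longer passed, 3 newly passed, 4 moved and 12 reversed. The 12 were medians of gene lists that passed neither in the main setting nor in the alternative and that crossed the median of random lists. The median of random lists itself changed with the setting. With a −log10 q of at least 3, the endothelium (1.06%), proximal tubule (0.964%) and striated muscle (0.673%) lay below it. The erythroid cells (1.33%) and the loop of Henle and distal tubule (1.38%) lay above it. Striated muscle also lay below it with a flank of 5 kb (0.420%) and as peaks per 10 kb (0.274). Without matching on length, erythroid cells (1.44%) lay above it and neurons (1.37%) below it. Restricted to autosomal genes, a choice made after the data were seen, erythroid cells (1.58%) lay above it. Neurons (1.37%) and the endothelium (1.65%) then lay below it. With 1 bp of overlap the Spearman correlation of signal was 0.20 in place of 0.26. With a promoter window of 2.5 kb the exon ratio was 1.12. The number of gene lists above random lists, 1 in the main setting, was 3 with a flank of 5 kb and 0 with a flank of 50 kb, and ranged from 1 to 2 when either replicate was left out. The lists concerned were the differentiating nephron (4.16%, adjusted permutation p = 0.175 with 50 kb), the ureteric bud and collecting duct (adjusted permutation p = 0.0125 with 5 kb and 0.0397 without replicate 1) and the nephron progenitors (adjusted permutation p = 0.0272 with 5 kb). Over all alternatives, adjusted permutation p ranged from 0.0017 to 0.175, from 0.0125 to 0.424 and from 0.0272 to 0.899 for these lists. The number of lists below random lists was 1 throughout, the olfactory receptors. The cause was not tested for any of these changes. The difference between kidney and other-organ genes kept its sign and passed in each setting, with p from 0.00073 with pooled peaks to 0.0393 within length classes. Leaving out a replicate means using the other replicate's own peak list, so it tests the list and not the spread between animals. No paired analysis was possible because the samples form 1 group. All listed alternatives were run. The unknown read depth limits any reading of why the replicates share few weak peaks.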

Other observations

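The gene families, stitched regions and Hox and motif tests were chosen after the peak lists had been seen. So were all tests of explanations for the few peaks on X, with the draws of autosomal peaks. The same holds for the tests of explanations for the overlap between replicates and for the higher coverage downstream of start sites. Hox genes, which pattern the body axis, were the most covered of 16 families: the median of 39 genes was 24.9% of gene body and flanks (28.2% in replicate 1 and 18.8% in replicate 2), against 1.57% for length-matched random lists (adjusted permutation p = 0.0011). Notch receptors and ligands (9 genes, 11.5%, adjusted permutation p = 0.0011), Smad genes of TGF-β signalling (8 genes, 6.17%, adjusted permutation p = 0.0134), retinoic acid receptors and enzymes (12 genes, 5.40%, adjusted permutation p = 0.0176), Wnt ligands (19 genes, 4.50%, adjusted permutation p = 0.0368) and cytosolic ribosomal proteins (76 genes, 3.97%, adjusted permutation p = 0.0056) also lay above random lists. Vomeronasal receptors (326 genes, 0%, adjusted permutation p = 0.0011) and Zfp genes (365 genes, 1.30%, adjusted permutation p = 0.0247) lay below. The Irx and Pax genes, the sine oculis homeobox family, claudins, collagens, keratins, solute carriers and immunoglobulin-like lectins did not pass. The Hox and receptor families lie in clusters, so that members share peaks and these p-values are too small. Neighbouring members of other families, such as the Zfp genes, can share flanks too, which was not examined. The families were also picked with some of their members already known to be among the most covered genes or widest regions, such as Hoxb3, Rara, Notch1 and Smad7. Without the members that the report or this section names, those that overlap the 10 stitched regions below and the most and least covered gene of each Hox cluster, the Notch family (7 genes, 6.30%, adjusted permutation p = 0.0823) and the Smad family (6 genes, 3.97%, adjusted permutation p = 0.173) no longer passed. The other families above or below random lists still did, with adjusted permutation p from 0.0016 to 0.0411, among them the Hox family with 19 genes at 23.5%. The 20 kb flanks of these Hox genes can hold left-out neighbours and the same peaks. For this family the check therefore cannot separate picked members from the others.

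Joined across gaps of up to 5 kb, replicated peaks formed 30250 regions, of which 372 spanned more than 20 kb. The region with the most covered sequence overlapped the neighbouring genes Col4a1 and Col4a2, which encode basement membrane collagens, on chromosome 8 from 11248367 to 11348262, with 56 peaks over 50.6 kb. Regions at Shb (43.8 kb), Gse1 (38.2 kb), Ski (37.8 kb), Smad3 (37.0 kb), Msi2 (35.7 kb), Ncor2 (34.7 kb), Tns1 (34.7 kb), the Hoxa cluster from Hoxa1 to Hoxa7 (34.3 kb) and Zfp608 (33.9 kb) followed.

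The scarcity of peaks on chromosome X was weighed against 3 technical explanations. A lower gene density was argued against, since X held 0.119 replicated peaks per gene and the lowest autosome, chromosome 7, 2.08, and gaps and repeats were argued against, since X held 1.30 peaks per Mb of unmasked sequence and chromosome 3 held 28.5. A common factor that puts X signal under the calling threshold was not decided: at equal rank per unmasked Mb, X peaks had 0.634 to 0.698 of the autosomal signal, but random autosomal peaks, drawn in the number X has, also gave ratios below 0.9 that varied across ranks by less than the bound set for X in 60% of 1000 draws. At 11 of 12 ranks at most 1.4% of draws were nonetheless as weak as X, with none at ranks 10, 20, 50 and 100 in either replicate (at rank 5, signal 4.20 on X against a median of 5.33 in replicate 1 and 4.42 against 4.97 in replicate 2), but at rank 200 of replicate 2 the signal was 3.04 for both and 52.5% of draws were at or below X. X copy number in pools of both sexes, the control and chromatin of the inactive X stay open, and no biological explanation was tested by the design.

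For the low sharing of peaks between replicates, narrower peaks in replicate 2 as the whole cause were argued against, since 49.6% of peaks at most were shared even with 1 bp required. Peaks near the calling threshold remain a candidate explanation, since with 1 bp of overlap required the strongest 10% were shared 2.25 times as often as the weakest 10% in the replicate with the lower ratio, and 2.80 times in the other. The strongest 10% were also wider, with a median of 659 against 252 bp in replicate 1 and 391 against 194 bp in replicate 2. Strength and width therefore cannot be told apart here. Differences in depth or between the pools could not be tested with peak lists.

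Coverage at 1 to 2 kb from start sites was 13.5% downstream and 5.02% upstream, a ratio of 2.70. Further start sites downstream of the most upstream one were not decided as the cause. Among 8125 genes with a single start counted over protein-coding transcripts, the ratio was 2.61 (95% bootstrap interval 2.42 to 2.84). Starts of other transcripts were not counted, and the most upstream start of a gene can be one of them. Further starts may therefore remain downstream in these genes. GC content was argued against, since 5962 genes whose GC content at 1 to 2 kb differed by at most 2 percentage points between the sides had a ratio of 2.60 (2.40 to 2.83). Both intervals come from resampling single genes and not blocks. Because neighbouring genes share peaks, the intervals are likely too narrow. No biological explanation was tested by the design.

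A hypothesis that motifs of kidney transcription factors are enriched in distal replicated peaks was not decided. Of 45167 replicated peaks more than 2.5 kb from a start site, only the 10000 with the highest signal were taken. Windows of 500 bp at the deposited summits of 8457 of these were compared with windows 3000 bp away. Of 10 kidney motifs, 3 (HNF1, FOX and GRHL) lay above all 100 shuffled versions of themselves in peaks relative to flanking sequence. So did 2 of 8 motifs of other organs (MEF2 and PU.1) and 1 of 4 general motifs (NF1). Counts were low for HNF1 (15 windows in peaks and 7 in flanks), GRHL (17 and 4) and NF1 (15 and 1). The ratio of peaks to flanks was close to the highest shuffled ratio for FOX (1.19 against 1.18) and PU.1 (1.51 against 1.47). The windows differed in GC content, 50.9% in peaks and 46.7% in flanks.

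A second hypothesis was that Hox genes of the paralog groups 12 and 13 are covered less than those of groups 1 to 11. The median was 7.91% for 6 genes of groups 12 and 13 and 26.2% for the other 33, a difference of -18.3 percentage points (permutation test, p = 0.0028). It had the same direction in replicate 1 (9.52% against 28.7%) and in replicate 2 (6.10% against 19.8%). Hoxb13 was at 0% and Hoxb4 at 53.3%, both named after their values were seen. In the Hoxd cluster, however, the least covered gene was Hoxd1, of paralog group 1, at 7.25%, below Hoxd13 at 8.91% and Hoxd12 at 11.5%. Neighbouring Hox genes share peaks, so the p is too small, and the pattern may reflect position within the clusters as well as the genes themselves.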
